A study of Rattus norvegicus with 35 samples.

How the data were processed

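Gene expression was measured in 35 rat tissue samples, 11 normal mammary glands and 24 mammary tumours, each on an oligonucleotide array of the RAE230A design. On this design a gene is read by a probe set, a group of short probes whose brightness is summarised as a signal. The group of each sample was taken from its label, and samples keep their label titles here. The labels call the tumours frozen and do not say how the normal glands were kept. The labels name no animal, pairing, batch or date, and nothing in them says that the samples came from separate animals. The p-values therefore measure the spread between these samples, part of which may be technical.

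The deposited table holds an intensity on a linear scale for each of 15923 probe sets on each array. The software, background correction and scaling that the authors used are not given in the sources used here. The lowest deposited value was exactly 1, which 3601 of the values (0.648%) took, so low signals had been bounded before deposit. The median signal ranged from 158 to 176 over the arrays, and the array medians of the log2 values lay within 0.16 of each other. The deposited scaling was therefore kept.

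The 57 control probe sets were left out, which leaves 15866. Values under the 10th percentile of all values, a signal of 41.6, were set to that floor and log2 was taken. No filter on level was applied. A gene for which every array of a group lies at the floor has only a bound there, and its fold is given as "at least". Gene symbols came from the platform annotation, checked by Entrez identifier against the RefSeq table of assembly GRCr8. Of the identifiers, 12754 matched and 0 symbols changed. Of the probe sets, 12783 carry 1 symbol, 312 carry several and were not named, and 2771 have none in the table used. For each of the 10411 genes, the probe set with the highest mean over all arrays was used. Several probe sets read 1868 genes, and for 167 of these genes called probe sets went in opposite directions. No coordinates are given, since no genome build was named.

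Tumours and normal glands were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with trend and robust estimation) over all 35 arrays with no covariate. A probe set or gene was called at a Benjamini-Hochberg adjusted p under 0.05. Log2 changes are tumour minus normal and stand with their standard error (SE). On simulated arrays of the same 15866 probe sets, with 50 changed at each fold, the procedure recovered 28% of the smallest changes simulated, 88% of 1.5-fold changes, 96% of 2-fold and 100% of 4-fold changes. It called 0.0384% of the unchanged probe sets. All changed probe sets had a mean level more than 2-fold above the floor, so the recovery does not cover dimmer ones.

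Fixed gene lists, 34 in number, were tested with camera at its preset correlation of 0.01, two-sided and adjusted over the lists. Of the 830 symbols listed, 676 were measured. In a simulation with the proteasome list shifted by 0.5, that list was called and 0 of the 33 other lists were. Its probe sets were drawn independently of each other, so it does not show how often lists of correlated genes are called. Members of each list were counted at p-values adjusted over all probe sets and also adjusted over the list alone. The difference between tumours and normal glands in the mean of each list was also tested by permuting the array labels 100000 times. That permutation test was chosen after the data were examined.

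The spread between arrays was the root mean square deviation of an array from its group mean, corrected for group size, and compared with a two-sided permutation test. List scores, each the mean of members standardized across the 24 tumours, were related by Pearson and Spearman correlation with two-sided permutation p-values over 6 relations. Figures were drawn with matplotlib.

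The samples, tests, lists, named genes and the alternatives listed next were fixed before the data were examined. Named genes were the 12 largest rises and 12 largest falls among called genes that changed the same way against the 8 glands titled NewN and the 3 others. To these were added up to 2 members of each list with the largest change, up to 2 with the highest level, and a fixed panel. Hras of that panel is not analysed here. Other members of a list are named as examples, chosen after their values were seen. These alternatives covered the array scaling, the floor, dim probe sets, the spread model, blocks by the number in the title, the normal glands used, an adipocyte score as covariate, title numbers held by more than 1 tumour, the correlation in camera and the probe sets per gene. Alternatives without the tumour titled X22L, without the glands titled NewN4, NewN6 and X27.1N, and with only the 8 NewN glands were chosen after the data were examined.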

Results

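The series compared normal rat mammary glands with mammary tumours. The labels name N-methyl-N-nitrosourea (NMU), an alkylating carcinogen used to induce mammary tumours in rats, as the model. The 11 normal samples comprise 8 glands titled NewN, the glands titled X27.1N and X28.1N, and a gland titled Young. The 24 tumours carry titles that begin with X. The signal median of an array averaged 167 ± 2.63 (SD, n = 11) in normal glands and 169 ± 4.24 (SD, n = 24) in tumours. The number of arrays limits the precision of every value.

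The distribution of signals differed between the groups, and so did 1 of 2 measures of RNA quality. The 10th percentile of signal was 38.2 ± 2.66 in normal glands and 43.6 ± 2.59 in tumours (SD), and the 90th percentile was 718 ± 38.6 and 596 ± 46.1. Both differences had a two-sided permutation p of 1e-05, the smallest that 100000 permutations can give. The ratio of 3' to 5' signal of the Gapdh controls, which rises as RNA degrades, was 1.13 ± 0.126 in normal glands and 1.02 ± 0.0795 in tumours (permutation p = 0.00264), while that of the Actb controls was 1.35 ± 0.11 and 1.26 ± 0.136 and did not pass (permutation p = 0.0645). These differences in signal range and in the Gapdh ratio run in parallel with the groups for every gene list given here. They were larger for the NewN glands, and X27.1N, X28.1N and Young lay nearer the tumours. Their Gapdh ratios were 0.963, 1.05 and 1.07, against 1.05 (NewN2) to 1.39 (NewN1) in the NewN glands. The 10th percentiles were 42.3, 40.8 and 41.3, against 33.4 (NewN1) to 39.0 (NewN8). The 90th percentiles were 639, 668 and 695, against 716 (NewN5) to 763 (NewN7). The median correlation between arrays was 0.948 within normal glands, 0.941 within tumours and 0.858 between the groups. It was 0.976 among the 8 NewN glands (range 0.928 to 0.987) and 0.937 between these and the 3 other normal glands (range 0.905 to 0.959). By the median the NewN glands were closer to each other, though the ranges overlap. The highest correlation between any pair of arrays was 0.987, so no array was a copy of another.

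The comparison asked which genes differ between tumours and normal glands. On the floored log2 scale, Mmp3 rose most and Fabp4 fell most among the named genes. The floor limits the changes of genes such as Rbp4 in tumours and Mmp7 and Mup5 in normal glands. This order therefore holds on that scale only. Of 15866 probe sets, 9238 (58.2%) were called, 5239 higher and 3999 lower in tumours. The larger changes were mostly falls: 259 probe sets were at least 2-fold higher and 806 at least 2-fold lower, and 25 were at least 4-fold higher against 247 lower. By gene, 6136 of 10411 were called, 3269 higher and 2867 lower. Among calls, 56.7% were higher, but with only the 7933 brightest probe sets tested 43.7% were. With the adipocyte score as a covariate, which had a correlation of -0.97 with group, 18 probe sets were called, and against the glands X27.1N and X28.1N alone 439 were higher and 927 lower. Named genes that passed under quantile normalization and not here included Krt5 (0.84), Spint2 (0.62), Xbp1 (0.53), Igfbp2 (0.98), Fdps (0.37), Hsp90ab1 (0.25) and Rpl7a (0.10).

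The largest rise on the floored scale among the named genes was that of Mmp3 (stromelysin 1, a matrix metalloproteinase). It went from a signal of 141 ± 84.1 (SD, n = 11) to 2382 ± 1488 (SD, n = 24), a log2 change of 3.97 (SE 0.29, adjusted p = 7.54e-14). Mmp13 (a collagenase) rose by 3.59 (SE 0.40) and Mmp7 (matrilysin) by 2.43 (SE 0.38). All 24 tumours lay above every normal gland for Mmp3 and Mmp13, and 23 did for Mmp7. Mmp13 was at the floor in 9 normal glands and Mfsd2a in 9. Mmp7 was at the floor in all 11 normal glands, so it was at least 5.38-fold higher. Msln (mesothelin, a cell surface protein) rose by 3.20 (SE 0.33), Penk (proenkephalin, a precursor of opioid peptides) by 3.16 (SE 0.30), Serpine2 (a serine protease inhibitor) by 2.87 (SE 0.26) and Spp1 (osteopontin) by 2.75 (SE 0.31). Mfsd2a (a lipid transporter) rose by 2.58, Gpx2 (a glutathione peroxidase of epithelia) by 2.53 and Mia by 2.47. Htr5b (a serotonin receptor gene) was at the floor in all 11 normal glands and at least 5.43-fold higher in tumours. Mup5 rose by 3.47 (SE 0.52) from the floor in 10 normal glands, but major urinary protein genes are close copies, so this value is uncertain as to the gene.

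Genes of fat cells fell in the tumours more than any other fixed list. Of 22 measured adipocyte genes, 0 rose, 19 fell and 3 did not pass the test. Adjusted over the list alone, 1 rose and 19 fell. The median log2 change of the list was -3.92 (camera adjusted p = 3.32e-19, and adjusted p = 0.0149 with an estimated correlation). Fabp4 (the fatty acid binding protein of adipocytes) went from a signal of 4363 ± 1117 in normal glands to 86.8 ± 186 in tumours (SD), a log2 change of -6.13 (SE 0.32, adjusted p = 5.3e-18). Cfd (adipsin, -6.10, SE 0.41), Cd36 (a fatty acid transporter, -5.03, SE 0.26) and Pnpla2 (adipose triglyceride lipase, -4.65, SE 0.25) fell. Dgat2 (triglyceride synthesis, -3.92) and Lpl (lipoprotein lipase, -3.93) fell. Outside the list, Aoc3 (-5.92), Rbp4 (retinol binding protein, -5.79), Trarg1 (-5.21), Ces1d (a carboxylesterase, -5.21) and Sncg (gamma synuclein, -4.77) fell. For each of these 11 genes all 24 tumours lay below every normal gland, and many tumours were at the floor: 23 each for Rbp4 and Trarg1, 16 each for Cd36 and Ces1d, 14 each for Fabp4 and Aoc3, 10 for Pnpla2 and 5 for Cfd.

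Lipogenic and fatty acid oxidation genes fell as well. Of 14 lipogenesis genes 2 rose, 11 fell and 1 did not pass, with the same counts adjusted over the list alone (median -1.31, camera adjusted p = 1.1e-05, and adjusted p = 0.221 with an estimated correlation). Scd (stearoyl-CoA desaturase, -4.90, SE 0.31), Thrsp (-4.26, SE 0.42) and Fasn (fatty acid synthase, -1.42, SE 0.18) fell, while Acly (ATP citrate lyase) fell less (-0.37, SE 0.12, adjusted p = 0.00934). The members that rose were Fads2 (0.85) and Scd2 (0.30). Of 17 fatty acid oxidation genes 15 fell and 2 did not pass, also adjusted over the list alone (median -0.73, camera adjusted p = 8.11e-08, and adjusted p = 0.263 with an estimated correlation). Etfb (electron transfer to the respiratory chain, -1.65, SE 0.13), Decr1 (-1.26, SE 0.10), Ech1 (-0.73) and Acaa2 (-0.53) fell. The call of Acly and that of Acaa2 were lost under quantile normalization, where their changes were -0.09 and -0.24.

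Genes of mitochondrial respiration fell. Of 29 oxidative phosphorylation genes 28 fell, 0 rose and 1 (Cox5a) did not pass, also adjusted over the list alone. The median was -0.50 (camera adjusted p = 3.35e-11, and adjusted p = 0.322 with an estimated correlation). Ndufs1 (complex I, -1.01, SE 0.14) and Sdha (complex II, -0.93, SE 0.08) fell, each with all 24 tumours below every normal gland. Cox8a (complex IV, -0.54) and Atp5f1b (ATP synthase, -0.40) fell. Under quantile normalization 20 fell, 0 rose and 9 did not pass, and the list median was -0.26 (camera adjusted p = 7.86e-07). Of 17 glycolysis genes 5 rose, 5 fell and 7 did not pass, also adjusted over the list alone, and the list was not called (adjusted p = 0.971). Its median was 0.16 and its mean -0.02. Pfkfb3 (a regulator of glycolytic flux, -2.27), Slc16a1 (a lactate transporter, -1.46) and Aldoa (-0.41) fell, while Eno1 rose by 0.70. Quantile normalization ended the call of Aldoa (-0.17).

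**Figure D1:**
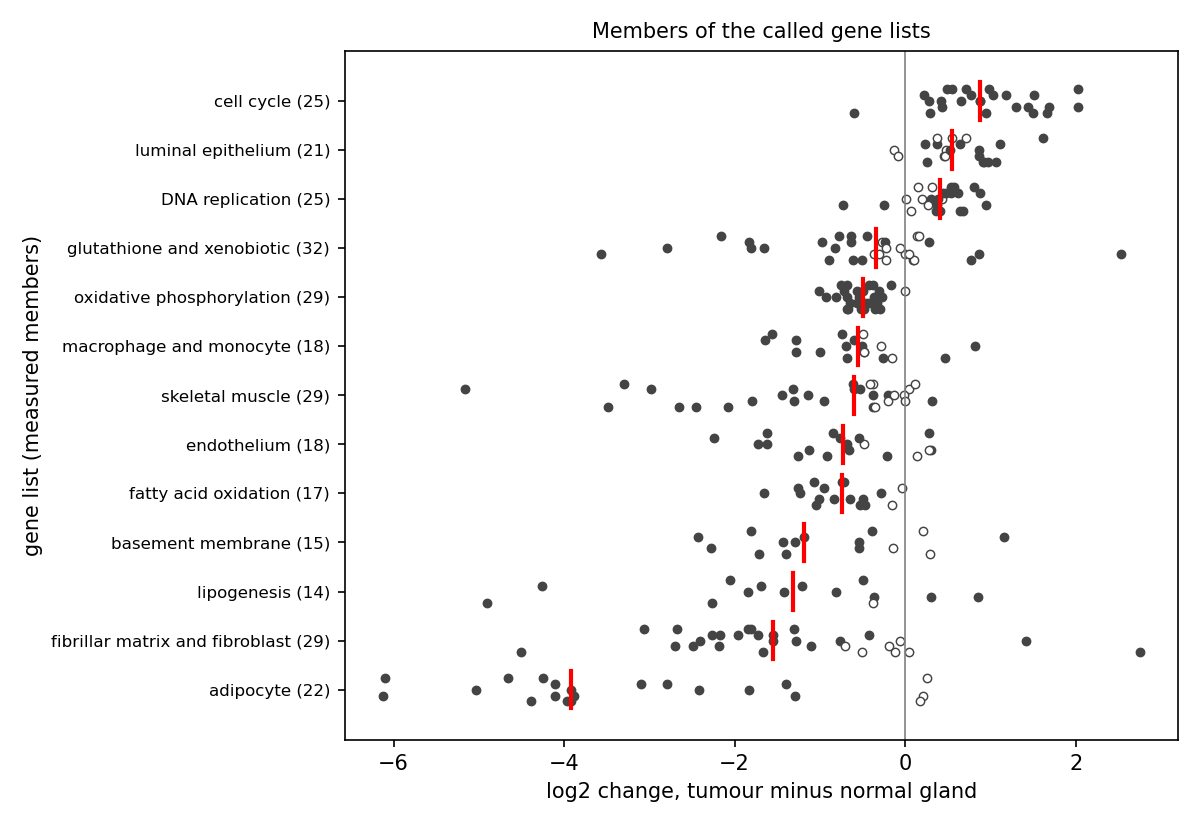
Log2 change (tumour minus normal gland) of each measured member of the 13 called gene lists, with the number of members in parentheses. Filled points are called genes, open points are not, and the red bar is the list median, from -3.92 for adipocyte genes to 0.88 for cell cycle genes.

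Connective tissue genes fell while a few matrix proteases rose. Of 29 fibrillar matrix and fibroblast genes 2 rose, 21 fell and 6 did not pass, also adjusted over the list alone. The median was -1.55 (camera adjusted p = 0.000816, and adjusted p = 0.682 with an estimated correlation). Dpt (dermatopontin, -4.51, SE 0.45), Dcn (decorin, a collagen-binding proteoglycan, -3.06, SE 0.59) and Sparc (-1.80, SE 0.32) fell, while Mgp changed by 0.04 (adjusted p = 0.947). The members that rose were Spp1 and Tnc (tenascin C, 1.42). Of 15 basement membrane genes 1 rose, 11 fell and 3 did not pass, and adjusted over the list alone 2 rose and 11 fell (median -1.19, camera adjusted p = 0.00251, and adjusted p = 0.558 with an estimated correlation). Nid2 (nidogen 2, -2.43), Lama2 (a laminin chain, -2.28) and Col4a1 (type IV collagen, -0.54) fell, and the gene that rose was Lama5 (1.16). Col4a1 was not called under quantile normalization (-0.29), and against X27.1N and X28.1N alone the basement membrane list was not called (median -0.37, adjusted p = 0.1).

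The matrix protease list held changes in both directions. Of its 23 genes 6 rose, 9 fell and 8 did not pass, also adjusted over the list alone, and the list was not called (adjusted p = 0.961). Its median was -0.30 and its mean 0.15, with the test pointing lower. Mmp3, Mmp7 and Mmp13 rose together with Mmp12 (1.34), Adamts1 (1.58) and Plaur (0.55). Ctsb (cathepsin B) fell by 0.54, and Mmp14 changed by -0.32 (adjusted p = 0.22).

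**Figure D2:**
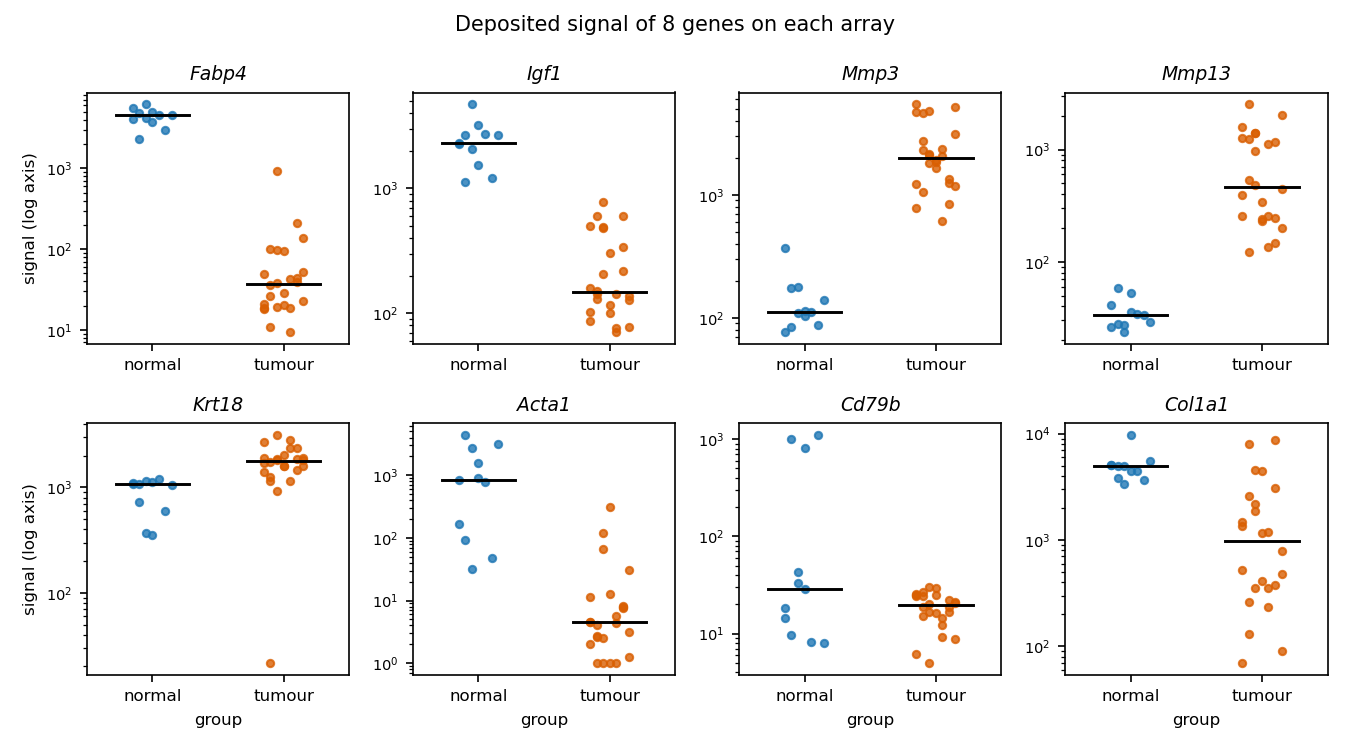
Deposited signal (log axis) of 8 genes on each array, in 11 normal glands and 24 tumours, with a bar at the group median. Fabp4 and Igf1 lie lower and Mmp3 and Mmp13 higher in all 24 tumours than in any normal gland, Cd79b is high in 3 normal glands, and the tumour lowest for Krt18 (21.5) is X22L.

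Genes of blood vessels and macrophages were lower in tumours. Of 18 endothelial genes 2 rose, 13 fell and 3 did not pass, also adjusted over the list alone (median -0.72, camera adjusted p = 0.000239, and adjusted p = 0.221 with an estimated correlation). Lyve1 (a lymphatic vessel receptor, -2.25), Kdr (the main VEGF receptor, -1.72) and Mcam (-1.62) fell, while Podxl changed by -0.49 (adjusted p = 0.0883). Of 18 macrophage and monocyte genes 2 rose, 12 fell and 4 did not pass, also adjusted over the list alone (median -0.55, camera adjusted p = 0.0123, and adjusted p = 0.679 with an estimated correlation). Csf1r (the receptor that maintains macrophages) fell by 1.64 with all 24 tumours below every normal gland, Laptm5 (-1.56) and Cd74 (-0.51) fell, while Lyz2 changed by -0.49 (adjusted p = 0.0816). The members that rose were Fcgr3a (0.82) and Aif1 (0.47). Without the glands NewN4, NewN6 and X27.1N the macrophage list was not called (adjusted p = 0.0593), nor was Cd74 (-0.31), and the macrophage list was not called either with only the 11900 brightest probe sets (adjusted p = 0.059). With only the 7933 brightest neither the macrophage list (adjusted p = 0.11) nor the endothelial list (adjusted p = 0.0765) was called.

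Lymphocyte genes were high in 3 of the normal glands. The signal of Cd79b, part of the B cell receptor, was 809 in NewN4, 1111 in NewN6 and 1013 in X27.1N, and at most 42.9 in the 8 other normal glands. Of 20 T and NK cell genes 4 rose, 6 fell and 10 did not pass, and of 5 B and plasma cell genes 3 fell and 2 did not pass, both also adjusted over the list alone. Neither list was called (adjusted p = 0.423 and 0.429, medians -0.31 and -1.24). Ccl5 (-1.28), Ptprc (CD45, -1.18), Cd37 (-1.68) and Ptprcap (-1.27) fell, while Cd2 rose by 0.42, Thy1 changed by -0.71 (adjusted p = 0.162) and Cxcr5 by 0.20 (adjusted p = 0.141). Without those 3 glands Ptprc (-0.43) and Ptprcap (-0.10) were not called, and the T and NK cell median was 0.23.

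Of 16 mast cell and granulocyte genes 3 rose, 3 fell and 10 did not pass, also adjusted over the list alone (adjusted p = 0.961, median 0, mean -0.21). Cma1 (chymase, -3.12) and Cpa3 (carboxypeptidase A3, -1.98) fell, both mast cell proteases and Cma1 at the floor in 15 tumours, while Tpsb2 changed by 0.12 (adjusted p = 0.525). Of 24 antigen presentation and interferon genes 5 rose, 4 fell and 15 did not pass, and adjusted over the list alone 5 rose and 3 fell (adjusted p = 0.961, median 0.06). The class II genes RT1-Db1 (-0.78) and RT1-Bb (-0.73) fell, and B2m changed by 0.07 (adjusted p = 0.427). Without NewN4, NewN6 and X27.1N neither class II gene was called (-0.38 and -0.29), nor was either under quantile normalization (-0.56 and -0.52).

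Skeletal muscle genes fell. Of 29 skeletal muscle genes 1 rose, 19 fell and 9 did not pass, and adjusted over the list alone 1 rose and 20 fell (median -0.60, camera adjusted p = 0.000155, and adjusted p = 0.558 with an estimated correlation). Acta1 (skeletal muscle actin) had a signal from 32.2 to 4427 among the normal glands, was at the floor in 21 tumours and fell by 3.48 (SE 0.51). Against X27.1N and X28.1N alone the muscle list was not called (median 0, adjusted p = 0.105). Car3 (carbonic anhydrase 3, abundant in muscle and in fat, -5.16), Myh1 (-0.37) and Tpm2 (-0.60) fell, the calls of Myh1 and Tpm2 being lost under quantile normalization (-0.07 and -0.34). Of 12 nerve and Schwann cell genes 5 rose, 3 fell and 4 did not pass, also adjusted over the list alone (adjusted p = 0.971). Its median was 0.11, its mean -0.57 and its test pointed lower. S100b (which adipocytes also express, -5.27, SE 0.28) and Pmp22 (-2.08) fell, while Cnp changed by 0.15 (adjusted p = 0.579). Of 4 erythrocyte genes 2 rose, 1 fell and 1 did not pass, also adjusted over the list alone (adjusted p = 0.423, median 0.26). Hbb (beta globin) fell by 1.13 and Car2 rose by 0.87.

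Genes of luminal epithelial cells rose. Of 21 genes 13 rose, 0 fell and 8 did not pass, also adjusted over the list alone (median 0.55, camera adjusted p = 0.0123, and adjusted p = 0.682 with an estimated correlation). Krt7 rose by 1.62 (SE 0.28), Krt19 by 1.11 (SE 0.38), Krt8 by 0.93 (SE 0.33) and Cd24 by 1.07 (SE 0.22), the keratins being those of simple epithelia, while Spint2 changed by 0.38 (adjusted p = 0.201). The tumour X22L lay below every normal gland for Krt8 and Krt19, and without it 19 genes rose, 0 fell and 2 did not pass, Spint2 (0.52) being called. Against the 8 NewN glands alone 6 rose, 1 fell and 14 did not pass, the list was not called (adjusted p = 0.205), and neither Krt8 (0.72) nor Krt19 (0.78) was. Without X27.1N and X28.1N the list was not called either (adjusted p = 0.0754).

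**Figure D3:**
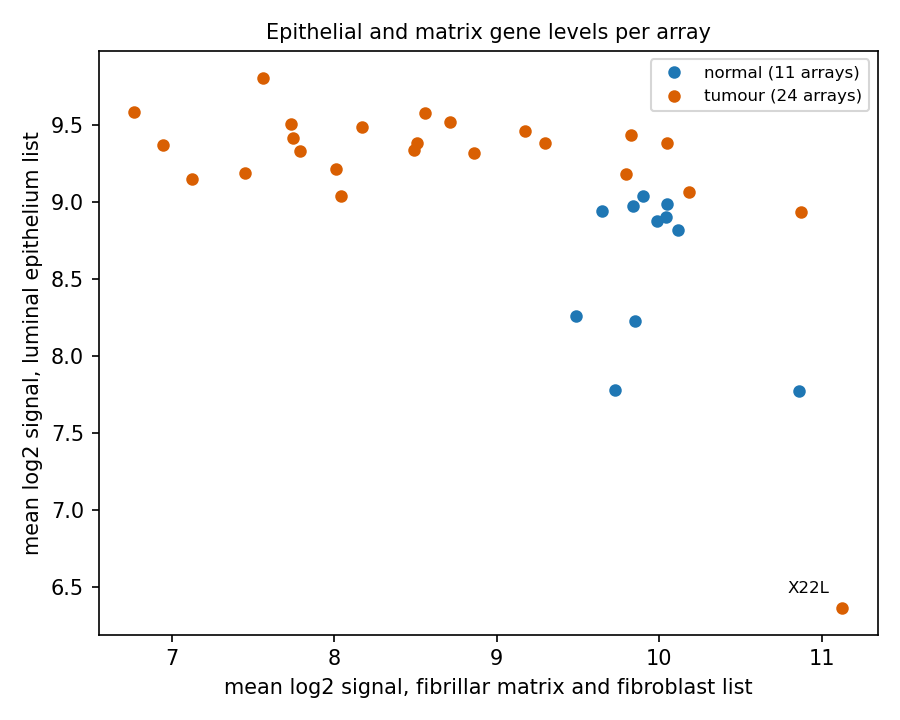
Mean log2 signal of the luminal epithelium list (vertical axis) against that of the fibrillar matrix and fibroblast list (horizontal axis) for each array, with 11 normal glands and 24 tumours as points. The tumour X22L has the highest matrix mean of the 24 tumours and lies apart at the lower right.

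Of 16 basal and myoepithelium genes 0 rose, 7 fell and 9 did not pass, also adjusted over the list alone, and the list was not called (median -0.40, adjusted p = 0.0525). It was called without Young (adjusted p = 0.034), without X27.1N and X28.1N (0.0221), without NewN4, NewN6 and X27.1N (0.0333), against the NewN glands alone (0.0117), with a lower floor (0.0433) and with array weights (0.0173). Other alternatives left it without a call. Among them were quantile normalization, leaving out X22L, and an estimated correlation (camera adjusted p = 0.682). So were the glands X27.1N and X28.1N alone and a block on the 4 arrays X27, X27.1N, X28 and X28.1N. Oxtr (the oxytocin receptor, -3.89, SE 0.15) and Myh11 (smooth muscle myosin, -2.60, SE 0.42) fell, Oxtr being at the floor in 22 tumours. Krt5 changed by 0.59 (adjusted p = 0.11) and Krt14 by -0.07 (adjusted p = 0.863), but Krt5 was called without X22L (0.76) and under quantile normalization (0.84).

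Milk genes did not move together. Of 11 milk protein genes 2 rose, 1 fell and 8 did not pass, and adjusted over the list alone 1 rose and 1 fell (adjusted p = 0.961). The median was -0.39 and the mean 0.04, with the test pointing higher. Xdh fell by 1.18, while Csn1s1 (-0.84, adjusted p = 0.094), Csn2 (-0.39, adjusted p = 0.629) and Csn3 (0.39, adjusted p = 0.413), which encode caseins, did not pass.

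Receptors and targets of hormones split. Of 19 hormone response genes 9 rose, 4 fell and 6 did not pass, and adjusted over the list alone 10 rose and 4 fell, with no call for the list (median 0.26, adjusted p = 0.47). Ccnd1 (cyclin D1) rose by 1.69 (SE 0.16, adjusted p = 7.38e-11), Prlr (the prolactin receptor) by 1.21 (SE 0.33) and Pgr (the progesterone receptor) by 0.91 (SE 0.24). Esr1 (the oestrogen receptor) changed by -0.23 (adjusted p = 0.317), and its signal was only 87.6 ± 49.8 in normal glands (SD). Ghr (the growth hormone receptor, -4.16, SE 0.15), Igfbp4 (-2.04) and Igfbp5 (-0.52) fell, Ghr being at the floor in 19 tumours, and Xbp1 changed by 0.25 (adjusted p = 0.111). Quantile normalization ended the call of Igfbp5 (-0.39).

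Of 17 ERBB and RAS signalling genes 9 rose, 2 fell and 6 did not pass, also adjusted over the list alone, with no call for the list (median 0.28, adjusted p = 0.0732). Dusp6 (a phosphatase induced by ERK signalling) rose by 1.80 (SE 0.12, adjusted p = 3.53e-15), all 24 tumours lying above every normal gland, and the ligand gene Areg (amphiregulin) by 1.49 (SE 0.37). Erbb2 rose by 0.51 (SE 0.15), though against the 8 NewN glands alone it was not called (0.26), and Egfr changed by -0.19 (adjusted p = 0.342), its 2 probe sets pointing in opposite directions (-0.19 and 0.63).

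Cell division genes rose. Of 25 cell cycle genes 24 rose and 1 fell (Cdc25b), also adjusted over the list alone (median 0.88, camera adjusted p = 2.5e-07, and adjusted p = 0.398 with an estimated correlation). Cdk1 (the mitotic kinase) rose by 2.03 (SE 0.29), Ube2c by 2.02 (SE 0.33), Mki67 (a proliferation marker) by 0.98 (SE 0.23) and Stmn1 by 0.88 (SE 0.17). Of 25 DNA replication genes 16 rose, 2 fell and 7 did not pass, and adjusted over the list alone 17 rose and 2 fell (median 0.41, camera adjusted p = 0.00186, and adjusted p = 0.558 with an estimated correlation). Mcm5 rose by 0.95, Tk1 by 0.88, Pcna by 0.53 and Mcm7 by 0.48.

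Most of these genes rose less against the 3 normal glands outside the NewN group. There Mki67 changed by 0.12 (1.31 against NewN), Tk1 by 0.17 (1.14), Mcm5 by 0.39 (1.16), Pcna by 0.25 (0.64), Ube2c by 0.90 (2.44), Cdk1 by 1.03 (2.41) and Stmn1 by 0.65 (0.96), while Mcm7 rose more there (0.57) than against NewN (0.45). The mean log2 level of the cell cycle list was 7.82 in X27.1N and 7.83 in Young, within the range of the tumours. In X28.1N it was 6.63, below every tumour (lowest 7.13, in X4), so not all 3 glands had a high level. Against X27.1N and X28.1N alone the cell cycle list was called (median 0.53), but the DNA replication list was not (median 0.19, adjusted p = 0.158).

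Of 16 growth arrest genes 3 rose, 8 fell and 5 did not pass, and adjusted over the list alone 3 rose and 9 fell (median -0.32, adjusted p = 0.29). Cdkn2a (which encodes p16 and ARF) was at the floor in all 11 normal glands and above every normal gland in all 24 tumours, at least 4.6-fold higher. Klf4 (-2.09), Txnip (-0.81) and Btg1 (-0.64) fell. Of 22 apoptosis regulators 4 rose, 6 fell and 12 did not pass, and adjusted over the list alone 4 rose and 5 fell (median -0.01, adjusted p = 0.961). Xiap (-0.71), Casp8 (-0.61) and Tnfrsf1a (-0.52) fell, while Mcl1 changed by -0.19 (adjusted p = 0.199). Without NewN4, NewN6 and X27.1N Casp8 was not called (-0.14). Under quantile normalization 6 apoptosis regulators rose and 4 fell (median 0.05).

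Of 15 IGF axis genes 3 rose, 6 fell and 6 did not pass, also adjusted over the list alone (median -0.02, adjusted p = 0.251). Igf1 fell by 3.53 (SE 0.33) with all 24 tumours below every normal gland. Igf2 rose by 0.79 (SE 0.26), though its 4 probe sets ranged from -1.11 to 0.79 and it was not called without NewN4, NewN6 and X27.1N (0.20). Against the 3 normal glands outside the NewN group it was -0.04. Igfbp2 changed by 0.70 (adjusted p = 0.113) and was called without X22L (0.93). Of 29 WNT and TGF-beta genes 9 rose, 9 fell and 11 did not pass, and adjusted over the list alone 10 rose and 9 fell (median -0.04, mean 0.01, adjusted p = 0.961). Wnt4 rose by 1.16 and Ctnnb1 (beta catenin) by 1.09, Ltbp1 fell by 1.23, and Inhbb changed by -0.16 (adjusted p = 0.737). The change of Ctnnb1 was 1.41 against the NewN glands and 0.24 against the 3 other normal glands, and its 4 probe sets ranged from 0.26 to 1.09. Under quantile normalization 5 IGF axis genes rose and 5 fell (median 0.19), and 11 WNT and TGF-beta genes rose and 6 fell (median 0.15).

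Detoxification genes fell. Of 32 glutathione and xenobiotic genes 4 rose, 16 fell and 12 did not pass, and adjusted over the list alone 4 rose and 18 fell (median -0.34, camera adjusted p = 0.00186, and adjusted p = 0.372 with an estimated correlation). Sod3 (extracellular superoxide dismutase, -3.57, SE 0.20) and Gpx3 (plasma glutathione peroxidase, -2.79, SE 0.33) fell, while Gpx2 rose. Sod1 fell by 0.44 but was not called under quantile normalization (-0.18), and Gstp1 changed by -0.31 (adjusted p = 0.0573).

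Housekeeping lists were not called. Of 32 ribosomal protein genes 7 rose, 4 fell and 21 did not pass, and adjusted over the list alone 4 rose and 3 fell (median 0.04, adjusted p = 0.939). Rpl12 rose by 0.30, Rps9 fell by 0.25 but was not called under quantile normalization (-0.16), and Rpl7a (0.06, adjusted p = 0.291) and Rps6 (0.05, adjusted p = 0.334) did not pass. Of 22 proteasome genes 3 rose, 10 fell and 9 did not pass, also adjusted over the list alone (median -0.18, adjusted p = 0.251). Psmc5 (-0.47) and Psmd9 (-0.39) fell, Psmb3 rose by 0.32, and Psma6 changed by -0.05 (adjusted p = 0.618) but by 0.24 under quantile normalization. Of 27 folding and ER stress genes 3 rose, 11 fell and 13 did not pass, and adjusted over the list alone 3 rose and 10 fell (median -0.09, adjusted p = 0.312). Asns (asparagine synthetase, -1.14) and Ddit3 (-0.81) fell, Calr rose by 0.22, and Hsp90ab1 changed by 0.02 (adjusted p = 0.881). The counts of the proteasome and folding lists turned over with the scaling, and those of the ribosomal list moved further towards rises. Under quantile normalization 14 ribosomal protein genes rose and 0 fell (median 0.09), 10 proteasome genes rose and 3 fell (median 0.09), and 13 folding and ER stress genes rose and 2 fell (median 0.14), again with no list called.

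Of 22 immediate early genes 7 rose, 6 fell and 9 did not pass, also adjusted over the list alone (median 0.12, mean -0.06, adjusted p = 0.971, the test pointing lower). Dusp1 fell by 1.13 and Junb rose by 0.52, while Egr1 changed by -0.34 (adjusted p = 0.101). Of 13 cholesterol synthesis genes 5 rose, 2 fell and 6 did not pass, also adjusted over the list alone (median 0.17, mean -0.15, adjusted p = 0.831, the test pointing higher). The genes that fell were Insig1 (-3.05) and Pmvk (-1.25). Cyp51 rose by 0.20 and Fdps changed by 0.18 (adjusted p = 0.315).

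Probe sets of some other named genes disagreed. The lowest and highest had opposite signs for Aif1 (-1.23 and 0.47), RT1-Bb (-0.73 and 0.04), B2m (-0.45 and 0.07), Cyp51 (-0.19 and 0.20) and Hsp90ab1 (-0.31 and 0.02). They had the same sign but differed in size for Igfbp5 (-2.11 and -0.52), Dusp1 (-1.13 and -0.26), RT1-Db1 (-0.78 and -0.23), Myh1 (-0.85 and -0.09), Mcl1 (-0.65 and -0.19), Podxl (-0.49 and -0.15), Thy1 (-0.71 and -0.35), Mup5 (1.10 and 3.48), Dusp6 (1.31 and 2.37), Prlr (0.64 and 1.29), Scd2 (0.09 and 1.29), Plaur (0.02 and 0.55) and Tk1 (0.57 and 0.88).

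In all, camera called 13 of 34 lists, 3 higher and 10 lower, and with an estimated correlation it called the adipocyte list alone. In the permutation test of list means, 20 of 34 lists passed after adjustment, 4 higher and 16 lower, and this test, chosen after the data were examined, does not compare a list with other genes. Among these were all 13 lists that camera called and 7 that it did not. The mean of the ERBB and RAS list was 0.41 higher and those of the growth arrest list (-0.26), the IGF axis list (-0.75) and the nerve list (-0.57) were lower, each at an adjusted p of 2.62e-05. The means of the IGF axis and nerve lists stand apart from their medians (-0.02 and 0.11), with Ghr, Igf1 and S100b among the members that fell most. The basal and myoepithelium list (-0.78, adjusted p = 0.000476), the B and plasma cell list (-0.81, adjusted p = 0.00963) and the folding and ER stress list (-0.13, adjusted p = 0.0184) were lower as well. Without NewN4, NewN6 and X27.1N the median of the B and plasma cell list was -0.00554 (-1.24 with them), and under quantile normalization the median of the folding and ER stress list was 0.14. The mean lay above every normal gland in 23 tumours for ERBB and RAS, and below every normal gland in 23 for nerve, 20 for the IGF axis and 16 for growth arrest.

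The next comparison asked whether tumours differ more from one another than normal glands do. The deviation of an array from its group mean was 0.33 ± 0.0863 (SD, n = 11) in normal glands and 0.36 ± 0.094 (SD, n = 24) in tumours, a difference of 0.03 that did not exceed the spread between arrays (two-sided permutation p = 0.379). The normal glands were not alike: NewN6 (0.44), X27.1N (0.45), X28.1N (0.42) and Young (0.43) deviated most. The other NewN glands deviated by at most 0.32 (NewN4). The test therefore does not show that normal glands of 1 kind vary as much as tumours. X22L had the largest deviation (0.73), and without it the difference was 0.01 (permutation p = 0.577).

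Across the 24 tumours, adipocyte and macrophage scores rose together. Pearson's r was 0.635 (permutation p = 0.00392, adjusted p = 0.0235) and Spearman's rho 0.66 (permutation p = 0.00064, adjusted p = 0.00384), over 6 relations. Without the tumours X10 and X15, the farthest from the median adipocyte score, r was 0.597 (adjusted p = 0.0159). With arrays centred on their medians r was 0.623 and no longer passed (adjusted p = 0.0684), while rho passed (adjusted p = 0.0087). Of the adipocyte genes, Cd36 was at the floor in 16 tumours, Fabp4 in 14, Pnpla2 in 10, Cfd in 5, and Dgat2 and Lpl in 0. A gene cannot tell apart the tumours in which it is at the floor. Whether macrophages express members of the adipocyte list was not examined, so the relation is one of scores and not of cell types. The other 5 relations among cell cycle, milk protein, adipocyte and macrophage scores did not pass, the strongest being cell cycle with milk protein (r = -0.377, adjusted p = 0.208, and rho = -0.327, adjusted p = 0.36). No label names a batch within which to repeat these relations.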

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

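The test on bacterial controls, the comparison of luminal with matrix genes, the test of adipocyte genes and that of endothelial genes in X22L were chosen after their results had been seen, as were the bootstrap interval of the oxidative phosphorylation list and the comparison of bacterial controls by normal gland. The other tests of this part were written before.

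Of 57 control probe sets, which take no part in the comparisons, 10 differed between the groups by more than 1.5-fold at an adjusted p under 0.05, 9 of them higher in tumours. The log2 differences of the bacterial controls were 1.12 for the dap 5' probe set (mean signal 11.7 in normal glands and 19.4 in tumours), 0.84 for phe 3' (26.7 and 46.5) and 0.71 for the middle of thr (168 and 284), and for TrpnX they were 0.86 at the 3' end, 0.66 at the 5' end and 0.64 in the middle. The middle of LysX was lower in tumours, by -0.76 (48.4 and 28.3). The Gapdh controls differed by 0.73 at the 5' end (2430 and 4124) and 0.72 in the middle, and the control for X12957 by 0.91 (113 and 214).

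Slightly more probe sets were higher than lower in tumours (56.7% of calls), and among the 3967 dimmest 1414 were higher and 481 lower. The median difference of the bacterial controls, which match no rat gene, was 0.44 (quartiles 0.20 and 0.61, 23 of 27 higher). These controls were compared without the floor that was applied to the other probe sets. Their mean signals ranged from 10.9 to 253, while the highest mean among the 3967 dimmest probe sets was 85.2. A control difference below the floor has no counterpart on the floored scale. The controls therefore cannot decide whether a higher background at the dim end of the tumour arrays accounts for part of the small rises. Against the 3 normal glands outside the NewN group the 3967 dimmest probe sets rose by a median of 0.0340 (0.0318 to 0.0429 by gland), against 0.11 for the NewN glands. The bacterial controls, again without the floor, were also higher against those 3 glands (0.27, and 0.52 against NewN). Whether the scale of the NewN arrays accounts for the rise therefore cannot be told. Quantile normalization gave 60.9% higher, further from an even split, and met neither bound set for a difference in value distribution. No biological explanation was tested.

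Adipocyte, stromal and oxidative phosphorylation genes fell together, which a change in tissue makeup could bring about. Loss of adipocytes alone would keep luminal genes in pace with matrix genes, provided that adipocytes express neither list, which was not examined. The lists moved apart by 1.97 (95% bootstrap interval 1.21 to 2.70), which argues against that loss alone only under this condition. Whether oxidative phosphorylation genes fell beyond the adipocyte loss cannot be told, since their mean change was -0.51 without and -0.27 with the adipocyte score (95% interval -0.76 to 0.22). Under quantile normalization the median of the oxidative phosphorylation list was -0.26 (95% bootstrap interval -0.31 to -0.20), against -0.50 with the deposited scaling. The whole interval is a fall, which argues against a scaling difference that quantile normalization removes as the only cause. Whether array scaling accounts for part of the fall cannot be decided, as the interval lies around the bound of -0.25.

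X22L lay apart from the other tumours. Its mean log2 level of adipocyte genes was 6.87, a difference of -2.08 from the lowest normal gland, so a normal gland under a tumour label does not account for it. Its Gapdh 3' to 5' ratio ranked 19 of 24 (0.964), so degraded RNA does not either. A larger share of connective tissue and macrophages could account for its rank of 1 for both matrix and macrophage genes, but its rank of 11 for endothelial genes decides nothing. A different kind of tumour was not tested.

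The count of called probe sets was not reached by any other split of the arrays that was drawn. The real grouping gave 9238, the highest of the other splits 2111, and 1 of 100 splits, the real one, reached that count. The other splits mix both tissues, so this argues against a random grouping only and says nothing of other differences between the groups. Chance cannot be excluded for the count of called lists, where the real grouping gave 13, the highest other split 17, and 26 of 100 splits reached 13.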

How the results depend on the processing

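The alternatives without X22L, without NewN4, NewN6 and X27.1N, and with only the 8 NewN glands were chosen after seeing the data. The counts of called probe sets stayed within 1.5 times under both other scalings, both floors, both spread models, the random block, and without Young, X22L, X27.1N and X28.1N, or NewN4, NewN6 and X27.1N. The difference in spread between arrays ranged from -0.00262 to 0.0662 and never passed. Under quantile normalization 129 named genes kept direction and side of the threshold, 7 gained a call, 12 lost it and Psma6 reversed (0.24). Low signals limit the rest: with only the 7933 brightest probe sets, 4750 were called, 2077 of them higher, with 152 at least 2-fold higher and 471 lower, as fewer were tested. With median centring the adipocyte and macrophage relation no longer passed (r = 0.623); the cause was not tested. With an estimated correlation camera called 1 list, 0 higher (0 at unadjusted p under 0.05) and 1 lower (5 at unadjusted p under 0.05), as the test then allows for correlated genes.

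With a block on the 4 arrays X27, X27.1N, X28 and X28.1N alone, limma called 0 probe sets, 0 higher and 0 lower, and 0 at least 2-fold higher and 0 lower (2736 at unadjusted p under 0.05), as only 4 arrays remain. Of the 1065 2-fold calls 1037 kept their direction, while Rps9 (0.0348) and Cd74 (0.00711) reversed. The deviations of paired titles had correlations of 0.186 for X27, 0.251 for X28, 0.0387 for X25 and 0.357 for X29. Against X27.1N and X28.1N alone 1366 were called, 439 higher and 927 lower, 168 at least 2-fold higher and 516 lower, as fewer glands remain, and Rps9 reversed (0.0380). There the DNA replication, basement membrane and skeletal muscle lists lost their call, and the ERBB and RAS, T and NK cell and B cell lists gained it. Of these glands X27.1N alone was high in lymphocyte genes (Cd79b 1013, against 32.9 in X28.1N). The gained lymphocyte calls therefore rest largely on X27.1N. With the 4-array block the lost calls were DNA replication (adjusted p = 0.0565), basement membrane (0.144), skeletal muscle (0.832) and glutathione (0.0565).

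With the adipocyte score as a covariate, 18 probe sets were called, 4 higher and 14 lower, 4 at least 2-fold higher and 13 lower. The score is nearly a copy of the grouping (correlation -0.97), which widens every error, and the adipocyte list and its genes were left out. The direction of the test reversed for these lists, given with their medians: luminal epithelium -0.35, cell cycle -0.0341, DNA replication -0.26, ribosomal protein -0.13, fibrillar matrix 2.25, basement membrane 0.66, matrix proteases 1.57, endothelium 0.33, macrophage 0.69, skeletal muscle 0 and glutathione 0.33. Reversed genes were Ech1 0.23, Pmvk 0.0424, Krt19 -0.72, Cd24 -0.0260, Sparc 1.54, Xdh 0.36, Igfbp4 1.90, Igfbp5 0.96, Areg -0.54, Cdk1 -0.17, Ube2c -0.67, Stmn1 -0.50, Mcm5 -0.12, Pcna -0.40, Mcm7 -0.32, Klf4 0.54, Txnip 0.0462, Rpl12 -0.0707, Ddit3 0.85, Eno1 -0.22, Cox8a 0.33, Dpt 2.09, Dcn 3.54, Nid2 0.21, Lama2 1.495, Col4a1 0.90, Ctsb 1.16, Mcam 0.68, Csf1r 0.11, Cd74 0.38, Myh1 0.71, Tpm2 0.54, Pmp22 1.33, Hbb 0.86, Dusp1 0.50, Gpx3 2.81, Igf1 1.17, Ltbp1 0.26, Wnt4 -0.11, Krt8 -0.86 and Mki67 -0.24.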

Other observations

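The genes of this part were chosen after their values were seen, and the lymph node test was chosen after seeing the result. X22L had little signal of epithelial genes. Krt18 was 21.5 in X22L and 1834 ± 555 in the other 23 tumours (SD), Krt8 was 75.7 against 2348 ± 766, and Epcam was 98.5 against 2746 ± 519. Matrix genes were high: Aspn (asporin) was 1799 against 45.5 ± 76.8, Tnc 3236 against 186 ± 177, Thy1 4113 against 287 ± 335, Ctsk (cathepsin K) 3084 against 197 ± 218 and Lgals1 (galectin 1) 7345 against 675 ± 677.

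Further members of the lists changed as well. The glucose transporter gene Slc2a1 rose by 1.19 and the lactate exporter gene Slc16a3 by 1.37. Among metal-binding proteins Mt1 rose by 0.78 and Mt2A by 0.86, and the growth factor genes Tgfa and Ereg rose by 0.98 and 0.93. Timp2 and Timp3 (inhibitors of matrix proteases) fell, by -1.37 and -1.33.

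Lymphocyte genes were high in NewN4, NewN6 and X27.1N alone. The hypothesis was lymph node tissue in those samples. The glands highest for T cell genes and those highest for B cell genes shared 3 of 3, but this had been seen before the test and inflammation would give it as well, so the test decides nothing. The median change of T and NK cell genes was -0.31 with those glands and 0.23 without them.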
